A study of Mus musculus with 23 samples.

How the data were processed

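Bulk RNA-seq libraries were made from 50 to 200 sorted cells each with a full-length polyA cDNA kit (SMART-Seq HT PLUS), per the labels' protocols, from C57BL/6 RORγt-EGFP embryos at embryonic day 14.5. Reads were trimmed with fastp, aligned with HISAT2 to GRCm39 and counted with featureCounts, per the submitters' processing notes, which give no versions and no strand, multi-mapping or overlap settings. Genes with near-identical copies or overlaps are therefore uncertain. The 2 deposited tables are called normalized counts by name, but the values the authors deposited are log2 values. They go below 0 (lowest −2.29 and −2.11), reach 17.80 and 18.90, and are exactly 0 in every library for 24259 and 26145 of 55061 listed genes. Base 2 was inferred, as the values raised as powers of 2 gave similar sums in all libraries of a table. The transform is not given in any source. Genes with few reads lie on a gene-specific floor, so a difference against a group near that floor depends on the transform, and log2 differences of low genes are approximate. The files hold no read totals, so depth per library is unknown and no counting interval is given. Recovery of whole reads, planned for linear values, was not attempted, because the transform is unknown and the floor differs by gene. The GRCm39 annotation was not used here, so no coordinates are given, and gene symbols are those of the files.

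Samples were grouped by the labels. All 23 columns matched a sample. The RORγt-negative group carries CD127-positive and Runx3-negative in its description, which its cell type label does not repeat. The test had been planned for linear normalized counts as limma-trend on log2(value + 1). Because the values were already log2, limma-trend (limma 3.58.1 in R 4.3.3, lmFit and eBayes with trend and robust) was run on the deposited values with no pseudocount. All libraries of a table entered 1 fit with the group as the only term and 10 and 4 residual degrees of freedom. Genes with a mean value of at least 3.32 (10 on the linear scale) over the libraries of the table were tested, 12890 in the first table and 15852 in the second. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. No block was used, because the sample numbers were not shown to pair the samples. The 9 comparisons, the tests and their alternatives, the gene lists and the rule for named genes were chosen before the data were examined.

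Named genes were the sort genes Rorc, Il7r, Itga4, Itgb7, Kit, H2-Aa, H2-Ab1 and Cd74, the 6 largest rises and 6 largest falls among called genes with a mean of at least 5.64 (50 on the linear scale) over both groups and no overlap between the libraries of both groups (predicted genes, Rik clones and pseudogenes left out), and up to 3 members with the smallest p of each list described. Col1a1 and Alb, and the basophil, Y-linked and list-member genes whose levels are given beside groups, were chosen after their values were seen. The 19 lists were LTi and type 3 effector, ILC progenitor, early progenitor, ILC2, ILC1 and natural killer, MHC class II, dendritic and antigen-presenting cell, B lineage, T lineage, Notch, proliferation, migration receptor, erythroid, hepatocyte, myeloid and mast cell, megakaryocyte, stroma and epithelium, immediate-early (stress) and mitochondrially encoded genes. Lists with 5 or more tested members were tested with camera (preset correlation 0.01), adjusted over 90 tests in the first table and 76 in the second, beside camera with an estimated correlation and fry. Genes called between RORγt-high and RORγt-negative cells were tested as sets in the knockout comparison. Lists of basophil, Y-linked and plasmacytoid dendritic cell genes were added after seeing the data.

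Alternatives were pseudocounts on the linear scale, no filter and a stricter filter on low values, TMM and median-of-ratios rescaling (own implementations on the values raised as powers of 2), only both groups in the fit, array weights, an absolute log2 difference of at least 1, the sample number as a block, an estimated list correlation, and each library left out in turn. Where a library was left out of a pair, the remaining one was assumed to vary like the other groups. The fit was tested on simulated data with 100 genes changed per fold size. For RORγt-mid against RORγt-negative cells (12890 genes), 31 of 100 genes changed by 1 on the log2 scale and 69 of 100 changed by 2 were recovered, with 4 false calls. For CD127+ MHC class II+ against CD127+ MHC class II− cells (15852 genes), 12 and 54 were recovered, with 3 false calls. For LTi against CD127+ MHC class II− cells (15852 genes), 11 and 49 were recovered, with 2 false calls. Camera called 2%, 3% and 2% of unchanged lists in these comparisons and 100% of lists raised by 1. The simulated genes varied independently, so these shares do not hold for lists whose genes vary together. In the first table the estimated correlation was 0.828 for mitochondrially encoded genes and 0.108 for LTi effector genes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.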

Results

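RNA was sequenced from small pools of 50 to 200 sorted cells of C57BL/6 mouse embryos at embryonic day 14.5 that carried an EGFP reporter of RORγt. RORγt, encoded by Rorc, is the transcription factor that lymphoid tissue inducer (LTi) cells and other group 3 innate lymphoid cells (ILC) require, and LTi cells start the formation of lymph nodes. The 23 libraries fell into 8 groups, and 2 deposited tables hold them. The first table has 15 libraries, 3 in each of 5 groups. Of these, RORγt-negative, RORγt-mid and RORγt-high cells were lineage-negative, α4β7-integrin-positive fetal liver cells sorted by EGFP, a further group was RORγt-mid cells of RORγt knockout embryos, and the last was LTi cells (lineage-negative, c-Kit-positive, EGFP-high), labelled with the fetus and not the liver as tissue. The descriptions of the RORγt-negative libraries add CD127-positive and Runx3-negative, so this group may differ from the others in more than EGFP. The second table has 8 libraries, 2 in each of 4 groups: EGFP-high liver cells that were CD127+ MHC class II−, CD127+ MHC class II+ or CD127− MHC class II+, and another 2 libraries of LTi cells. The series asks how these precursors mature as RORγt rises, and how uniform the RORγt-high cells are.

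Each value was on a log2 scale and normalized by the authors within its table, so log2 differences between groups were taken only within a table. Immediate-early levels of both tables are also set side by side, each against reference genes of the same library. The files give no read totals, and the depth of the libraries is unknown. Replicates of a group correlated across genes at 0.904 to 0.976 in the first table and at 0.963 to 0.986 in the second. RORγt-high replicate 3 lay farthest from its group mean (root mean square deviation 0.75 on the log2 scale) and held the basophil protease gene Mcpt8 at 7.83, against 0.63 and 0.74 in the other 2 RORγt-high libraries. RORγt-mid replicate 2 held Ms4a2, a chain of the high-affinity IgE receptor of basophils and mast cells, at 6.75, against 0.93 and 1.28. Its Mcpt8 was low, at 0.91, whereas RORγt-high replicate 3 also held Ms4a2, at 6.17. Differences are given as log2 difference ± standard error with the adjusted p of limma; levels are means ± SD. The labels do not say whether replicates came from separate animals, so each p measures only the spread between these libraries, which may be technical in part. In the first table the Y-linked gene Ddx3y ranged from 0.93 to 9.22 among RORγt-high libraries. It ranged as widely in the RORγt-negative (1.22 to 9.25), knockout (1.00 to 9.66) and LTi groups (2.10 to 10.27). Libraries within these groups therefore did not all come from the same embryos.

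The transcripts of the sort genes followed the sorts in part: Rorc parted RORγt-negative from RORγt-mid cells but not RORγt-mid from RORγt-high cells. Rorc stood at 10.31 ± 0.92 in RORγt-negative cells (n = 3) and 15.27 ± 0.12 in RORγt-mid cells (n = 3), a rise of 4.96 ± 0.32, adjusted p = 2.77e-07. RORγt-high cells, sorted for brighter EGFP, had Rorc at 15.22 ± 0.14, a difference from RORγt-mid of −0.05 ± 0.32, adjusted p = 0.948, whose sign turned to 0.02 without RORγt-mid replicate 1. LTi cells had Rorc at 15.01 ± 0.34, a difference from RORγt-high of −0.22 ± 0.32, adjusted p = 0.769. Il7r, which encodes the CD127 chain of the interleukin-7 receptor, fell from RORγt-negative to RORγt-mid cells by 1.84 (SE 0.32, adjusted p = 0.00227) and rose from RORγt-mid to RORγt-high cells by 3.66 ± 0.32, adjusted p = 7.14e-06. The Il7r fall may be set by the sort, because the RORγt-negative libraries are described as CD127-positive. Kit, the stem cell factor receptor, rose at the second step by 1.75 ± 0.27, adjusted p = 0.000659. The integrin genes Itga4 and Itgb7 were on in every group, and rose from RORγt-negative to RORγt-mid cells by 0.87 ± 0.14 and 1.18 ± 0.21 (adjusted p = 0.00138 and 0.00316).

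**Figure D1:**
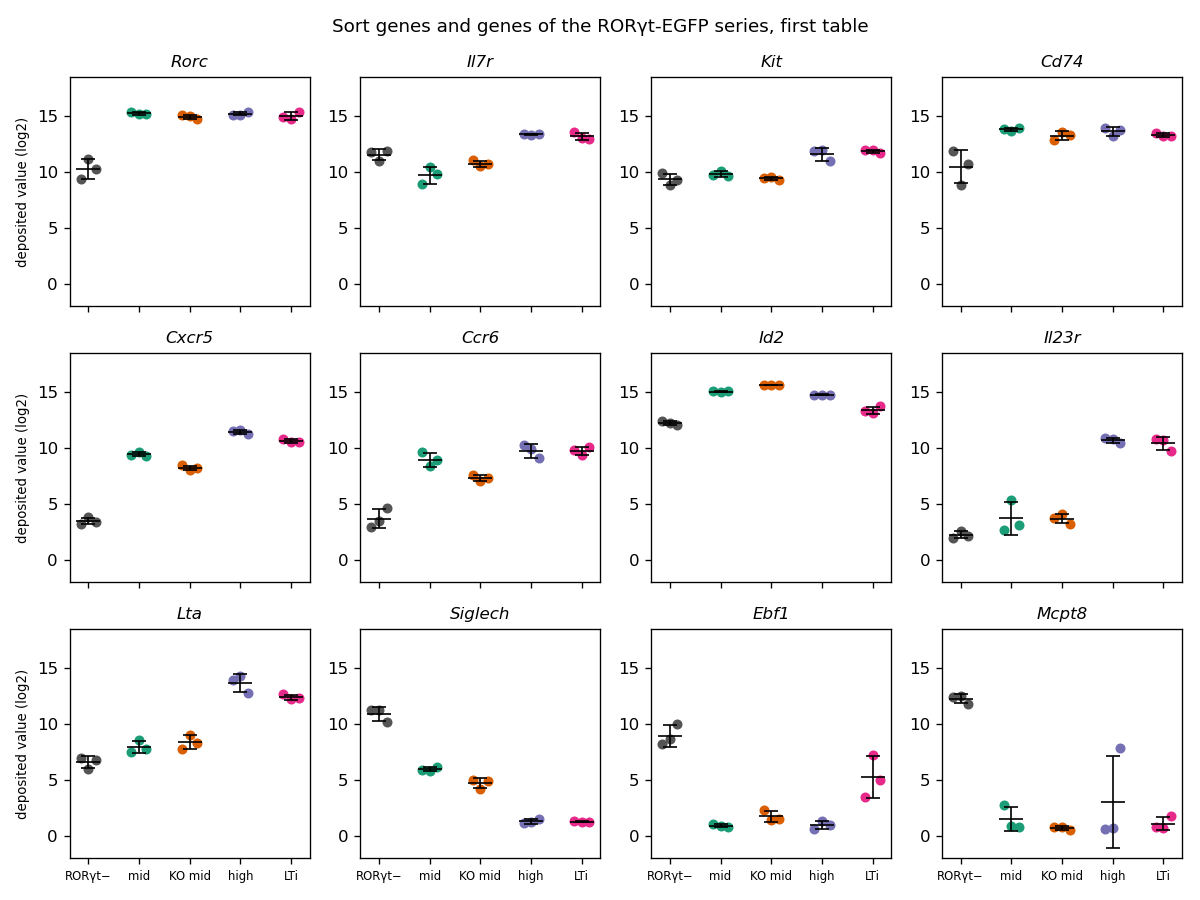
Deposited log2 value (y axis) of 12 genes in each library of the first table, by group (x axis; RORγt−, RORγt-mid, knockout RORγt-mid, RORγt-high, LTi); points are libraries, and bars the mean ± SD of 3 libraries. Rorc was at 10.31 in RORγt-negative cells and at 15.27 in RORγt-mid cells, and among the RORγt-high libraries Mcpt8 was high in 1.

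From RORγt-negative to RORγt-mid cells, the lists of LTi effector and ILC progenitor genes rose and that of B lineage genes fell. ILC1 and natural killer genes and MHC class II genes rose only at the preset correlation (adjusted p = 0.12 and 0.0695 with an estimated correlation). Cxcr5, the receptor for the follicle chemokine CXCL13, rose from 3.50 ± 0.29 to 9.45 ± 0.18 (n = 3 each; 5.95 ± 0.20, adjusted p = 3.07e-10), and Ccr6, the CCL20 receptor of LTi cells, rose by 5.28 ± 0.43, adjusted p = 4.78e-06. Id2, the inhibitor of E proteins that all ILC need, rose by 2.80 ± 0.13, adjusted p = 1.92e-08. Ebf1, the B cell specification factor, fell by 8.04 (SE 0.75, adjusted p = 1.28e-05) and Mcpt8 by 10.78 (SE 1.36, adjusted p = 0.000186). In all, 564 of 12890 tested genes were higher and 331 lower in RORγt-mid cells, and 2444 had an unadjusted p under 0.05. The largest other rises were in Lingo4, a membrane protein gene (5.94 ± 0.31), the chemokine gene Ccl5 (5.72 ± 0.68), Serinc2 (5.25 ± 0.35) and Il17re, a chain of the interleukin-17C receptor (5.18 ± 0.43). The largest other falls were in Ly6d, a surface marker of early B and plasmacytoid cells (−7.86 ± 1.03), Lilrb4b, an inhibitory receptor gene with a near-identical neighbour that can share its reads (−7.80 ± 1.04), Ms4a2 (−7.39 ± 1.45), the steroid-synthesis gene Cyp11a1 (−7.32 ± 0.93) and the lipoxygenase gene Alox15 (−7.23 ± 1.11). Without RORγt-mid replicate 1 the count of calls was 567.

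Of the LTi and type 3 effector list, 10 of 15 measured members rose and 0 fell (14 and 0 adjusted over the list alone). Their median log2 difference was 1.89 (camera adjusted p = 1.4e-16, adjusted p = 0.00471 with an estimated correlation). Cd4, carried by many adult LTi cells, rose by 4.03 ± 0.40. Among ILC progenitor genes 10 of 14 measured members rose and 1 fell (12 and 1 adjusted over the list alone). Over this list, the median log2 difference was 1.88 (camera adjusted p = 1.71e-12, adjusted p = 0.00578 with an estimated correlation). Tox, a factor of early ILC precursors, rose by 2.33 ± 0.19 and Runx3, a factor of ILC1 and ILC3, by 2.00 ± 0.20. The Runx3 rise may be set by the sort, because the RORγt-negative libraries are described as Runx3-negative. Of ILC1 and natural killer genes 6 of 13 measured members rose and 0 fell (9 and 0 adjusted over the list alone). The median of these log2 differences was 3.57 (camera adjusted p = 1.31e-08, adjusted p = 0.12 with an estimated correlation). Tbx21, which encodes the type 1 master regulator T-bet, rose by 4.66 ± 0.61, adjusted p = 0.000251, and Il2rb, the shared interleukin-2 and interleukin-15 receptor chain, by 4.03 ± 0.39, adjusted p = 1.65e-05. MHC class II genes rose too: 9 of 10 measured members rose and 0 fell (9 and 0 adjusted over the list alone). As a list, they had a median log2 difference of 1.81 (camera adjusted p = 6.82e-08, adjusted p = 0.0695 with an estimated correlation). The invariant chain gene Cd74 rose by 3.35 ± 0.49, H2-Eb1 by 3.19 ± 0.54, H2-Ab1 by 2.82 ± 0.52 and H2-Aa by 4.23 ± 0.83, and reads of these related genes can be shared.

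Of the B lineage list 0 of 9 measured members rose and 7 fell (0 and 9 adjusted over the list alone). For all of its members the median log2 difference was −2.50 (camera adjusted p = 3.39e-13, adjusted p = 0.00303 with an estimated correlation). The immunoglobulin signalling gene Cd79a fell by 6.65 (SE 0.82, adjusted p = 0.000148) and the immunoglobulin μ chain gene Ighm by 1.71 (SE 0.20, adjusted p = 7.97e-05). Of dendritic and antigen-presenting cell genes 2 of 17 measured members rose and 5 fell (3 and 7 adjusted over the list alone). Their median log2 difference was −0.36 (camera adjusted p = 0.0443, adjusted p = 0.293 with an estimated correlation). Siglech and Spib, both genes of plasmacytoid dendritic cells, changed by −4.93 ± 0.40 and −5.19 ± 0.69, whereas Batf3, a factor of conventional dendritic cells, rose by 3.61 ± 0.37. Among myeloid and mast cell genes 0 of 8 measured members rose and 3 fell (2 and 3 adjusted over the list alone; median log2 difference −0.74, camera adjusted p = 0.0224, adjusted p = 0.329 with an estimated correlation), and the mast cell carboxypeptidase gene Cpa3 fell by 5.06 (SE 0.73, adjusted p = 0.000531). Of early progenitor genes 0 of 15 measured members rose and 1 fell (0 and 2 adjusted over the list alone; median log2 difference −0.37, camera adjusted p = 0.0443, adjusted p = 0.367 with an estimated correlation), the 1 being Myb at −1.19 ± 0.20. Of ILC2 genes 2 of 7 measured members rose and 2 fell (2 and 2 adjusted over the list alone), with Gata3, a factor of ILC and T cells, up by 2.77 ± 0.35 and the cytokine gene Il4 at −3.40 ± 0.71 (median log2 difference −0.42, camera adjusted p = 0.664). Among Notch genes 1 of 7 measured members rose and 1 fell (2 and 1 adjusted over the list alone; median log2 difference 0.63, camera adjusted p = 0.315), and the ligand gene Dll1 rose by 5.08 ± 0.38. Of migration receptor genes 5 of 12 measured members rose and 2 fell (5 and 3 adjusted over the list alone; median log2 difference 0.47, camera adjusted p = 0.0118, adjusted p = 0.238 with an estimated correlation), and of proliferation genes 0 of 20 measured members rose and 1 fell (0 and 1 adjusted over the list alone; median log2 difference −0.17, camera adjusted p = 0.0103, adjusted p = 0.261 with an estimated correlation).

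The remaining lists did not differ by camera between RORγt-mid and RORγt-negative cells. For T lineage genes 4 of 10 measured members rose and 1 fell (5 and 2 adjusted over the list alone). Over this list, the median log2 difference was 1.15 (camera adjusted p = 0.0808). Stroma and epithelium genes had 3 risers and 1 faller among 5 measured members, with the keratin gene Krt8 up by 3.22 ± 0.60 (median log2 difference 1.52, camera adjusted p = 0.201). Of immediate-early genes 0 of 11 measured members rose and 1 fell (0 and 1 adjusted over the list alone). The median of these log2 differences was 0.31 (camera adjusted p = 0.443). No member passed among the 10 erythroid genes (median log2 difference 0.03, camera adjusted p = 0.514), the 10 hepatocyte genes (median log2 difference −0.28, camera adjusted p = 0.66), the 13 mitochondrially encoded genes (median log2 difference 0.39, camera adjusted p = 0.0567) and the 3 measured megakaryocyte genes, too few for camera. Of list calls in the first table, those that held with an estimated correlation were LTi effector and B lineage genes (RORγt-mid and RORγt-high against RORγt-negative), ILC progenitor genes (both of these comparisons), LTi effector and dendritic genes (RORγt-high against RORγt-mid), and immediate-early and proliferation genes (LTi against RORγt-high), 10 of 43. None of 27 held in the second table, where 12 list tests had an unadjusted p under 0.05 with that correlation and fry called 18 lists.

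From RORγt-mid to RORγt-high cells, the list of LTi effector genes rose and that of dendritic and antigen-presenting cell genes fell. Early progenitor and myeloid and mast cell genes fell only at the preset correlation (adjusted p = 0.0695 and 0.261 with an estimated correlation). Il23r, the receptor for the cytokine that drives ILC3, rose from 3.71 ± 1.45 to 10.72 ± 0.21 (n = 3 each; 7.0 ± 0.58, adjusted p = 5.76e-06), and Lta, which encodes lymphotoxin α, needed to form lymph nodes, rose by 5.74 ± 0.41, adjusted p = 1.95e-06. Csf1r, the growth factor receptor of macrophages, fell by 5.50 (SE 1.09, adjusted p = 0.00378), and Siglech by 4.69 (SE 0.40, adjusted p = 6.28e-06). Of 12890 tested genes 919 were higher and 826 lower in RORγt-high cells. Further rises were in the receptor phosphatase gene Ptprz1 (6.43 ± 0.49), the collagen gene Col18a1 (6.31 ± 0.83), Arhgef28 (6.12 ± 0.80) and the extracellular matrix gene Ecm1 (5.98 ± 0.73). Further falls were in the interferon-inducible gene Ifi205, which has close paralogs (−6.52 ± 0.78), Plbd1 (−6.26 ± 1.18), the chemokine gene Ccl4 (−4.97 ± 1.37), Bex6 (−4.78 ± 0.44) and Entpd1, which encodes the ectonucleotidase CD39 (−4.75 ± 0.76). The calls numbered 1154 without RORγt-mid replicate 1, 1090 without RORγt-high replicate 1 and 1146 without RORγt-high replicate 2. The Ccl4 call ended without RORγt-mid replicate 3 or RORγt-high replicate 1 or 2 (adjusted p up to 0.110).

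For the LTi and type 3 effector list 8 of 15 measured members rose and 0 fell (9 and 0 adjusted over the list alone), with median log2 difference 2.03, camera adjusted p = 1.83e-08, adjusted p = 0.0261 with an estimated correlation, and Cxcr5 rose further, by 2.03 ± 0.20. ILC progenitor genes also rose further, since 9 of 14 measured members rose and 1 fell (10 and 2 adjusted over the list alone). As a list, they had a median log2 difference of 2.04 (camera adjusted p = 4.16e-05, adjusted p = 0.0695 with an estimated correlation). Examples were the lymphocyte factor Ets1 (2.50 ± 0.18), the interleukin-18 receptor gene Il18r1 (2.28 ± 0.25) and Pdcd1, which encodes PD-1 and marks committed ILC precursors (1.90 ± 0.22). Of early progenitor genes 0 of 15 measured members rose and 7 fell (0 and 7 adjusted over the list alone; median log2 difference −0.97, camera adjusted p = 2.53e-06, adjusted p = 0.0695 with an estimated correlation), among them the transcription factor genes Mef2c (−2.16 ± 0.30) and Hhex (−0.89 ± 0.15) and the leukocyte antigen gene Cd48 (−1.01 ± 0.17). Dendritic and antigen-presenting cell genes fell: 1 of 17 measured members rose and 10 fell (2 and 10 adjusted over the list alone). For all of its members the median log2 difference was −2.57 (camera adjusted p = 1.46e-06, adjusted p = 0.0386 with an estimated correlation). Irf8, a factor of dendritic cells and monocytes, changed by −2.58 ± 0.22 and Itgax, which encodes CD11c, by −4.68 ± 0.41. In the MHC class II list 0 of 10 measured members rose and 3 fell (0 and 3 adjusted over the list alone). Their median log2 difference was −0.65 (camera adjusted p = 0.00105, adjusted p = 0.238 with an estimated correlation). Its fallers serve peptide loading: H2-DMa (−2.66 ± 0.21), H2-DMb1 (−3.36 ± 0.46) and H2-Ob (−3.23 ± 0.72), while Cd74 differed by −0.18 ± 0.49, adjusted p = 0.86. Among myeloid and mast cell genes 0 of 8 measured members rose and 3 fell (0 and 3 adjusted over the list alone; median log2 difference −1.64, camera adjusted p = 0.0064, adjusted p = 0.261 with an estimated correlation), with the macrophage gene Cd68 at −3.00 ± 0.36 and the granule protease gene Prtn3 at −4.15 ± 0.66.

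Of migration receptor genes in RORγt-high against RORγt-mid cells 5 of 12 measured members rose and 1 fell (5 and 1 adjusted over the list alone). Over this list, the median log2 difference was 0.51 (camera adjusted p = 0.0248, adjusted p = 0.261 with an estimated correlation). S1pr1, the receptor for exit into blood and lymph, rose by 1.84 ± 0.20 and the oxysterol receptor gene Gpr183 by 1.72 ± 0.20. Of the Notch list 2 of 7 measured members rose and 0 fell (3 and 0 adjusted over the list alone; median log2 difference 0.77, camera adjusted p = 0.0469, adjusted p = 0.212 with an estimated correlation), and Dll1 rose by 2.34 ± 0.38. Among stroma and epithelium genes 1 of 5 measured members rose and 0 fell (4 and 0 adjusted over the list alone; median log2 difference 0.94, camera adjusted p = 0.0469, adjusted p = 0.212 with an estimated correlation), the riser being Krt8 at 3.94 ± 0.60. For mitochondrially encoded genes 0 of 13 measured members rose and 0 fell (0 and 0 adjusted over the list alone). The median of these log2 differences was −0.68 (camera adjusted p = 0.00116, adjusted p = 0.452 with an estimated correlation). The other lists did not pass camera. Within them, the cytotoxic granule gene Gzma changed by −6.77 ± 1.28, the prostaglandin D synthase gene Hpgds by −3.70 ± 0.39, the T cell signalling gene Lat by 2.11 ± 0.24, Ighm by −1.74 ± 0.20 and the B cell adaptor gene Blnk by −3.96 ± 0.72. Called members went both ways in most of these lists. Risers and fallers were 3 and 1 of 7 ILC2 genes and 3 and 1 of 10 T lineage genes. They were 1 and 2 of 9 B lineage genes and 0 and 1 of 13 ILC1 and natural killer genes. The basophil transcripts in RORγt-mid replicate 2 and RORγt-high replicate 3 lay beside these differences. Without both libraries, an alternative chosen after seeing the data, 2309 genes were called.

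Over the whole span from RORγt-negative to RORγt-high cells, every measured gene of the LTi effector list rose, and the B lineage list fell. Dendritic, early progenitor and myeloid and mast cell genes fell only at the preset correlation (adjusted p = 0.0617, 0.0695 and 0.13 with an estimated correlation). Cxcr5 rose by 7.99 ± 0.20, adjusted p = 4.6e-12 (n = 3 each), Cd4 by 7.30 ± 0.40 and Lta by 7.12 ± 0.41. Cd79a changed by −8.35 ± 0.82, adjusted p = 4.95e-06, and Siglech by −9.61 ± 0.40, adjusted p = 1.2e-09. Calls were 1793 higher and 1320 lower of 12890. The largest other rises were in Il23r (8.46 ± 0.58), the T cell receptor γ constant gene Trgc1, whose paralogs can share reads (8.31 ± 0.91), Serinc2 (8.24 ± 0.35), Prr29 (7.57 ± 0.46) and Dll1 (7.42 ± 0.38). The largest other falls were in Ly6d (−10.75 ± 1.03), Mcpt8 (−9.21 ± 1.36), Ms4a2 (−7.96 ± 1.45) and Cox6a2, a gene of plasmacytoid dendritic cells (−7.74 ± 0.43).

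On the LTi effector list 15 of 15 measured members rose and 0 fell (15 and 0 adjusted over the list alone). As a list, they had a median log2 difference of 5.05 (camera adjusted p = 3.6e-17, adjusted p = 0.00471 with an estimated correlation). On the ILC progenitor list 13 of 14 measured members rose and 0 fell (13 and 0 adjusted over the list alone). For all of its members the median log2 difference was 3.56 (camera adjusted p = 1.04e-13, adjusted p = 0.00557 with an estimated correlation). Il18r1 rose by 4.03 ± 0.25 and Pdcd1 by 3.66 ± 0.22. Of B lineage genes 1 of 9 measured members rose and 8 fell (1 and 8 adjusted over the list alone; median log2 difference −5.64, camera adjusted p = 1.26e-07, adjusted p = 0.00578 with an estimated correlation), of dendritic genes 3 of 17 measured members rose and 12 fell (4 and 12 adjusted over the list alone; median log2 difference −2.93, camera adjusted p = 1.47e-05, adjusted p = 0.0617 with an estimated correlation) and of early progenitor genes 0 of 15 measured members rose and 10 fell (0 and 10 adjusted over the list alone). Their median log2 difference was −1.28 (camera adjusted p = 8.09e-07, adjusted p = 0.0695 with an estimated correlation). T lineage genes rose in RORγt-high against RORγt-negative cells: 8 of 10 measured members rose and 1 fell (8 and 1 adjusted over the list alone). Over this list, the median log2 difference was 1.67 (camera adjusted p = 0.00574, adjusted p = 0.139 with an estimated correlation). Trbc1 and Trbc2, near-identical T cell receptor β constant genes, rose by 2.34 ± 0.34 and 1.51 ± 0.19, and the costimulatory receptor gene Cd28 changed by −4.35 ± 0.36. Myeloid and mast cell genes fell: 0 of 8 measured members rose and 6 fell (0 and 6 adjusted over the list alone; median log2 difference −3.58, camera adjusted p = 3.77e-05, adjusted p = 0.13 with an estimated correlation), and of proliferation genes 0 of 20 measured members rose and 6 fell (0 and 6 adjusted over the list alone). The median of these log2 differences was −0.25 (camera adjusted p = 0.013, adjusted p = 0.262 with an estimated correlation). Of ILC1 and natural killer genes 7 of 13 measured members rose and 0 fell (8 and 1 adjusted over the list alone; median log2 difference 3.57, camera adjusted p = 0.00514, adjusted p = 0.367 with an estimated correlation), with the surface receptor gene Cd160 up by 5.85 ± 0.57. Of migration receptor genes 7 of 12 measured members rose and 2 fell (7 and 3 adjusted over the list alone; median log2 difference 1.03, camera adjusted p = 0.00124, adjusted p = 0.139 with an estimated correlation).

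LTi cells of the fetus differed from RORγt-high liver cells by far higher immediate-early genes, more of the cytokine genes Il22 and Il17f, and lower proliferation genes in the first table. As lists, neither the immediate-early nor the proliferation difference was seen against CD127+ MHC class II− cells in the second table (median log2 differences −0.41 and 0.23). Ptgs2, the inducible cyclooxygenase-2 gene, rose from 1.23 ± 0.19 to 11.13 ± 0.86 (n = 3 each; 9.89 ± 0.72, adjusted p = 2.58e-06). The stress-induced factor gene Atf3 rose by 8.73 ± 0.74, adjusted p = 9.43e-06, and the nuclear receptor genes Nr4a3 and Nr4a1 by 7.53 ± 1.11 and 7.25 ± 1.00. Single genes were mixed against CD127+ MHC class II− cells in the second table. Nr4a3 was higher in LTi cells there too (8.03 ± 0.31). Ptgs2, not called there, stood at 11.84 ± 0.02 against 8.72 ± 0.14, and Fos at 15.91 ± 0.22 against 16.00 ± 0.25. In the first table Il22, the barrier cytokine of ILC3, rose by 6.09 ± 0.75, adjusted p = 0.000328 and Il17f by 3.39 ± 0.57, adjusted p = 0.00378. LTi cells were higher for 335 genes and lower for 262 of 12890. The imprinted gene Mest rose by 6.27 ± 1.34, a call that ended without LTi replicate 2 (adjusted p = 0.0614). Falls were in the interferon-induced GTPase genes Tgtp2, which has a near-identical copy (−3.37 ± 0.91), and Irgm2 (−3.02 ± 0.39), in interferon-inducible Rtp4 (−3.20 ± 0.70), the histone gene H2ac6 (−2.76 ± 0.55), the natural killer receptor gene Klrd1 (−2.74 ± 0.66) and the chemokine receptor gene Ccr1 (−2.60 ± 0.42). Calls numbered 381 without RORγt-high replicate 1, 365 without LTi replicate 1 and 320 without LTi replicate 2. The Tgtp2 call ended without any library but LTi replicate 3 (adjusted p up to 0.176), the Rtp4 call without RORγt-high replicate 3 or LTi replicate 1 (up to 0.0752), and the Klrd1 call without RORγt-high replicate 1 or 3 or LTi replicate 1 or 2 (up to 0.119).

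Of immediate-early genes in LTi against RORγt-high cells 9 of 11 measured members rose and 0 fell (10 and 0 adjusted over the list alone). As a list, they had a median log2 difference of 2.91 (camera adjusted p = 4.87e-15, adjusted p = 0.0172 with an estimated correlation). The phosphatase gene Dusp1 rose by 2.65 ± 0.28 and the AP-1 gene Junb by 3.07 ± 0.35. Of proliferation genes 0 of 20 measured members rose and 7 fell (0 and 12 adjusted over the list alone). For all of its members the median log2 difference was −0.41 (camera adjusted p = 3.73e-09, adjusted p = 0.0271 with an estimated correlation). The mitotic genes Plk1, Ccnb1 and Aurkb changed by −1.04 ± 0.17, −0.92 ± 0.17 and −0.80 ± 0.15. For the LTi effector list 4 of 15 measured members rose and 1 fell (4 and 2 adjusted over the list alone). Their median log2 difference was 0.38 (camera adjusted p = 0.163). On the ILC progenitor list 1 of 14 measured members rose and 1 fell (2 and 1 adjusted over the list alone; median log2 difference −0.06, camera adjusted p = 0.85), Id2 changing by −1.37 ± 0.13 and the circadian and cytokine-controlled factor gene Nfil3 by 2.05 ± 0.34. Early progenitor genes gave 0 risers and 4 fallers of 15 (median log2 difference −0.06, camera adjusted p = 0.0567), with the cytokine receptor gene Flt3 at −2.03 ± 0.34. The chemokine receptor gene Cxcr4 rose by 2.08 ± 0.36. Markers of other cells differed between these tissues. Erythroid genes were lower (0 of 10 measured members rose and 1 fell (0 and 4 adjusted over the list alone); median log2 difference −2.39, camera adjusted p = 4.43e-05, adjusted p = 0.238 with an estimated correlation), as were myeloid genes (0 of 8 measured members rose and 1 fell (0 and 2 adjusted over the list alone); median log2 difference −2.08, camera adjusted p = 0.000226, adjusted p = 0.166 with an estimated correlation) with the macrophage gene Adgre1 at −2.22 ± 0.30. Of ILC1 and natural killer genes 0 of 13 measured members rose and 1 fell (0 and 3 adjusted over the list alone). Over this list, the median log2 difference was −1.24 (camera adjusted p = 0.0129, adjusted p = 0.412 with an estimated correlation). The epithelial adhesion gene Epcam rose by 4.93 ± 0.85, and the fibroblast collagen gene Col1a1 stood at 8.69 ± 2.97 in LTi libraries against 0.48 ± 0.59.

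**Figure D2:**
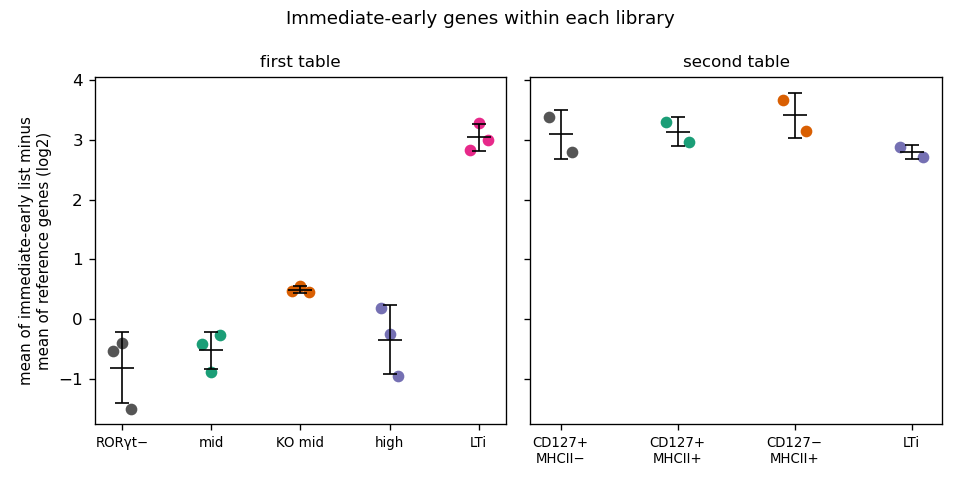
Mean of 11 immediate-early genes minus the mean of 9995 reference genes in the same library (y axis, log2) by group (x axis) in both tables; points are libraries, and bars the mean ± SD. In the first table LTi libraries stood at 3.04 and the liver groups between −0.81 and 0.50, and in the second every group stood between 2.79 and 3.41.

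In the knockout, Rorc stood at 15.09, 15.06 and 14.75 in the 3 knockout RORγt-mid libraries and at 15.40, 15.23 and 15.18 in the 3 wild-type RORγt-mid libraries (−0.30 ± 0.32, adjusted p = 0.728). The labels do not say which part of the gene was deleted or which isoform, so Rorc transcript does not check the labels. Knockout cells had lower levels of the cytokine gene Il17f and of several genes that rise with RORγt. Il17f fell by 3.91 (SE 0.57, adjusted p = 0.00579) with n = 3 each, Il17re by 2.68 (SE 0.43, adjusted p = 0.0106) and Serinc2 by 3.14 (SE 0.35, adjusted p = 0.00198). Cxcr5 fell by 1.21 (SE 0.20, adjusted p = 0.0121). Of 12890 genes 38 were higher and 107 lower, and 1901 had an unadjusted p under 0.05. Other large falls were in the growth factor receptor gene Pdgfrb (−3.27 ± 0.52), the syndecan gene Sdc4 (−2.79 ± 0.41), the potassium channel gene Kcnk1 (−2.33 ± 0.45) and Nr1d1, which encodes the clock repressor REV-ERBα (−2.26 ± 0.38). Rises were in Dusp1 (1.98 ± 0.28, adjusted p = 0.00478), the immediate-early factor gene Egr1 (2.88 ± 0.64), the tetraspanin gene Tspan8 (2.50 ± 0.56), the sterol-synthesis gene Msmo1 (1.57 ± 0.34), the channel gene Aqp9 (1.48 ± 0.31), the lymphocyte receptor gene Cd244a (1.42 ± 0.29) and Il17rb, the interleukin-25 receptor gene (3.39 ± 0.66).

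Single libraries weighed on the knockout comparison. Its 145 calls became 32, 32 and 42 without knockout replicate 1, 2 or 3, and 48, 84 and 78 without RORγt-mid replicate 1, 2 or 3. The share of higher genes, 26.2% of the 145, was 9.52% without knockout replicate 3, 36.9% without RORγt-mid replicate 2 and 16.7% to 28.2% without any other 1 of the 6 libraries. The calls of Pdgfrb, Serinc2, Sdc4, Il17f and Dusp1 held without any 1 library. Tspan8 and Aqp9 lost theirs without any 1 of the 6 (adjusted p up to 0.218 and 0.188). The Egr1 and Cd244a calls ended without any library but RORγt-mid replicate 3 (up to 0.190 and 0.157), that of Msmo1 without any but RORγt-mid replicate 2 (up to 0.151) and that of Il17rb without any but RORγt-mid replicate 1 (up to 0.139). Kcnk1 lost its call without knockout replicate 1 or 3 or RORγt-mid replicate 1 or 2 (up to 0.105), Il17re without knockout replicate 1 or 2 (up to 0.0586), Nr1d1 without knockout replicate 2 or RORγt-mid replicate 1 (up to 0.0651) and Cxcr5 without knockout replicate 2 or 3 (up to 0.0713).

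Among LTi effector genes in the knockout 0 of 15 measured members rose and 2 fell (0 and 4 adjusted over the list alone; median log2 difference −0.42, camera adjusted p = 0.00129, adjusted p = 0.163 with an estimated correlation), and Ccr6 differed by −1.66 ± 0.43, adjusted p = 0.08. Genes that rose with RORγt were over-represented among those lower in the knockout. Of the 107 genes lower in the knockout, 59 were higher in RORγt-high than in RORγt-negative cells, where independent lists would share 14.9 (Fisher's exact test across genes, p = 9.4e-24; genes are not independent replicates), and these comparisons share no library. As a set, the 1793 genes higher in RORγt-high cells had a median difference of −0.09 in the knockout, and 56.2% were lower (camera p = 0.00227, p = 0.0700 with an estimated correlation). The 1320 genes lower in RORγt-high cells had a median of 0.04 (camera p = 0.368, p = 0.589 with an estimated correlation). Single libraries moved these medians. The first was −0.17 without RORγt-high replicate 3 and −0.14 without RORγt-mid replicate 3. The second was 0.02 without RORγt-mid replicate 2 or RORγt-negative replicate 3, 0.03 without knockout replicate 3 or RORγt-high replicate 3, and 0.07 without RORγt-high replicate 1 or 2. Across all genes both differences correlated at r = −0.106 (Spearman's rho −0.0565).

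Markers of other cells also differed in the knockout. Hepatocyte genes were higher (0 of 10 measured members rose and 0 fell (0 and 0 adjusted over the list alone); median log2 difference 3.02, camera adjusted p = 1.97e-05, adjusted p = 0.263 with an estimated correlation), with the albumin gene Alb at 10.23 ± 2.06 against 6.57 ± 1.86 and at 12.61 in knockout replicate 3. Erythroid genes were higher as well (0 of 10 measured members rose and 0 fell (0 and 0 adjusted over the list alone); median log2 difference 1.61, camera adjusted p = 0.00231, adjusted p = 0.342 with an estimated correlation). Of immediate-early genes 2 of 11 measured members rose and 0 fell (4 and 0 adjusted over the list alone; median log2 difference 0.78, camera adjusted p = 7.16e-05, adjusted p = 0.173 with an estimated correlation), Dusp1 and Egr1 being the called risers. Of T lineage genes 0 of 10 measured members rose and 0 fell (1 and 0 adjusted over the list alone). The median of these log2 differences was 0.89 (camera adjusted p = 0.000616, adjusted p = 0.0695 with an estimated correlation). Mitochondrially encoded genes had none of 13 called (median log2 difference −0.62, camera adjusted p = 0.000359, adjusted p = 0.411 with an estimated correlation). Of proliferation genes 0 of 20 measured members rose and 1 fell (0 and 2 adjusted over the list alone; median log2 difference −0.24, camera adjusted p = 0.00251, adjusted p = 0.215 with an estimated correlation). Of migration receptor genes 0 of 12 measured members rose and 1 fell (1 and 4 adjusted over the list alone; median log2 difference −0.32, camera adjusted p = 0.0243, adjusted p = 0.261 with an estimated correlation), the faller being Cxcr5, whose call ended without knockout replicate 2 or 3 (up to 0.0713). No member of the ILC progenitor list passed the test over all genes (median log2 difference −0.14, camera adjusted p = 0.924).

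**Figure D3:**
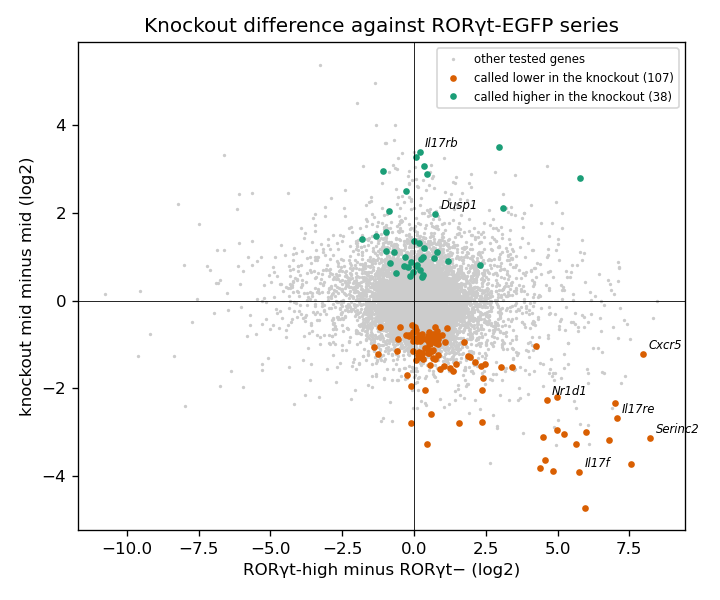
Log2 difference of each of 12890 genes between RORγt-high and RORγt-negative cells (x axis) against that between knockout and wild-type RORγt-mid cells (y axis); coloured points are the 107 genes called lower and the 38 called higher in the knockout. Of the 107 lower genes, 59 were also called higher in RORγt-high cells.

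Within RORγt-high liver cells that carried CD127, the MHC class II+ libraries had higher MHC class II genes, as sorted, and also higher Mcpt8, Prss34 and Ms4a2, genes of basophils. H2-Aa, an MHC class II chain, rose from 5.85 ± 0.53 to 13.80 ± 0.14 (n = 2 each; 7.95 ± 0.28, adjusted p = 0.000131). The basophil protease genes Mcpt8 and Prss34, the latter with close paralogs, rose by 8.96 ± 0.30, adjusted p = 0.000131 and by 8.94 ± 0.61, adjusted p = 0.00439, and Ms4a2 by 8.47 ± 0.22, adjusted p = 3.63e-05. The cytokine gene Il22 fell by 1.75 (SE 0.14, adjusted p = 0.00778). Of 15852 tested genes 20 were higher and 6 lower, and 1299 had an unadjusted p under 0.05. Other rises were in the complement factor H gene Cfh (5.69 ± 0.60), H2-Eb1 (5.55 ± 0.31), H2-Ab1 (4.87 ± 0.32) and Cd74 (4.02 ± 0.21). Among MHC class II genes 4 of 10 measured members rose and 0 fell (8 and 0 adjusted over the list alone). As a list, they had a median log2 difference of 2.93 (camera adjusted p = 5.23e-19, adjusted p = 0.0596 with an estimated correlation). Among myeloid and mast cell genes 1 of 13 measured members rose and 0 fell (10 and 0 adjusted over the list alone), with median log2 difference 4.32, camera adjusted p = 1.24e-14, adjusted p = 0.0672 with an estimated correlation, and the neutrophil and basophil protease gene Ctsg differed by 7.41 ± 0.98, adjusted p = 0.065. Hepatocyte genes were also higher (1 of 10 measured members rose and 0 fell (3 and 0 adjusted over the list alone); median log2 difference 1.16, camera adjusted p = 1.39e-06, adjusted p = 0.314 with an estimated correlation). T lineage genes had no called member (median log2 difference −0.79, camera adjusted p = 0.00485, adjusted p = 0.231 with an estimated correlation), nor had proliferation genes (median log2 difference −0.30, camera adjusted p = 0.00191, adjusted p = 0.559 with an estimated correlation). Calls numbered 15 without CD127+ MHC class II+ replicate 1, 10 without its replicate 2 and 10 without CD127+ MHC class II− replicate 2, with 93.3% or more of them higher (76.9% of the 26). The Il22 call ended without any 1 library (adjusted p up to 0.0797), that of Cfh without either MHC class II− library or MHC class II+ replicate 2 (up to 0.155), that of Prss34 without MHC class II− replicate 2 (0.0677) and that of H2-Ab1 without MHC class II+ replicate 2 (0.0559).

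RORγt-high cells without CD127 had more of the dendritic cell genes Cd209a and Itgax and less Il22 and Lta, while no list call held with an estimated correlation. Against CD127+ MHC class II+ cells, Cd209a, a lectin gene of dendritic cells, rose from 2.05 ± 0.03 to 11.50 ± 0.39 (n = 2 each; 9.45 ± 0.25, adjusted p = 1.28e-05) and Itgax by 8.08 ± 0.83, adjusted p = 0.00448, while Rorc differed by −0.19 ± 0.26, adjusted p = 0.736. Il7r fell by 3.42 (SE 0.25, adjusted p = 0.0013), as the gate sets, Il22 by 5.11 (SE 0.14, adjusted p = 1.28e-05) and Lta by 3.70 (SE 0.34, adjusted p = 0.00323). Calls were 317 higher and 432 lower of 15852. Other rises were in Rhpn1 (8.91 ± 0.49), the olfactory receptor gene Or10aa1, of a large gene family (8.38 ± 0.23), the vesicle protein gene Sv2b (8.24 ± 0.38) and Pcp4l1 (7.35 ± 0.51). All 6 of the largest falls were genes of basophils, mast cells or granulocytes: Prss34 (−8.95 ± 0.61), Mcpt8 (−8.63 ± 0.30), Ms4a2 (−8.59 ± 0.22), Cpa3 (−8.11 ± 0.84), the leukotriene-synthesis gene Alox5 (−7.18 ± 0.34) and Ctsg (−6.68 ± 0.98). The count was 209 without CD127+ MHC class II+ replicate 1, 232 without its replicate 2 and 1547 without CD127− MHC class II+ replicate 1 (31.2% of them higher, against 42.3% of the 749).

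Of ILC progenitor genes in CD127− MHC class II+ against CD127+ MHC class II+ cells 1 of 16 measured members rose and 6 fell (1 and 9 adjusted over the list alone). For all of its members the median log2 difference was −1.01 (camera adjusted p = 3.65e-06, adjusted p = 0.314 with an estimated correlation). The arginase gene Arg1, the chemokine receptor gene Cxcr6 and the precursor factor gene Tcf7 changed by −2.17 ± 0.12, −4.00 ± 0.23 and −2.04 ± 0.13. Of dendritic genes 6 of 17 measured members rose and 2 fell (7 and 2 adjusted over the list alone; median log2 difference 1.44, camera adjusted p = 6.44e-05, adjusted p = 0.231 with an estimated correlation), with the factor gene Irf4 up by 4.42 ± 0.50. MHC class II genes rose further: 6 of 10 measured members rose and 0 fell (9 and 0 adjusted over the list alone; median log2 difference 1.59, camera adjusted p = 6.66e-08, adjusted p = 0.105 with an estimated correlation), with H2-DMb1 up by 3.04 ± 0.33. T lineage genes were lower (0 of 10 measured members rose and 4 fell (0 and 4 adjusted over the list alone); median log2 difference −1.49, camera adjusted p = 0.00247, adjusted p = 0.231 with an estimated correlation), and Lat and the kinase gene Lck changed by −2.11 ± 0.20 and −1.80 ± 0.21. For proliferation genes 6 of 20 measured members rose and 0 fell (12 and 4 adjusted over the list alone). Their median log2 difference was 0.85 (camera adjusted p = 0.00191, adjusted p = 0.559 with an estimated correlation). LTi effector genes gave 0 risers and 3 fallers of 16 (median log2 difference −0.45, camera adjusted p = 0.0214, adjusted p = 0.67 with an estimated correlation). Of ILC2 genes 1 of 11 measured members rose and 2 fell (1 and 4 adjusted over the list alone; median log2 difference −0.92, camera adjusted p = 0.0237, adjusted p = 0.295 with an estimated correlation). Among ILC1 and natural killer genes 0 of 11 measured members rose and 2 fell (0 and 4 adjusted over the list alone; median log2 difference −1.24, camera adjusted p = 0.0129, adjusted p = 0.314 with an estimated correlation). Examples are the costimulator gene Icos (−2.80 ± 0.28) and the granule gene Nkg7 (−2.04 ± 0.18). Myeloid and mast cell genes fell (0 of 13 measured members rose and 3 fell (1 and 6 adjusted over the list alone); median log2 difference −5.57, camera adjusted p = 0.00294, adjusted p = 0.295 with an estimated correlation).

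Against the CD127+ MHC class II− cells, which differ in both gates, CD127− MHC class II+ cells had more H2-Aa and Cd209a and less Il22, with the basophil gene Mcpt8 low in both groups. The comparison with CD127+ MHC class II+ cells used the same 2 CD127− libraries, so these comparisons are not independent. H2-Aa rose by 9.82 ± 0.28, adjusted p = 2.03e-05 (n = 2 each), Cd209a by 9.37 ± 0.25, adjusted p = 1.8e-05 and the tryptophan-breakdown gene Kynu by 8.14 ± 0.99, adjusted p = 0.00518. Il22 fell by 6.86 (SE 0.14, adjusted p = 5.91e-06) and Ptprz1 by 5.88 (SE 0.27, adjusted p = 0.000173). Mcpt8 stood at 2.57 ± 0.39 and 2.24 ± 0.05. Calls were 645 higher and 508 lower of 15852 (55.9% higher). Without CD127− MHC class II+ replicate 1 there were 1704 calls and only 37.9% were higher, so the balance turned. Rhpn1, Or10aa1 and Sv2b rose by 8.84 ± 0.49, 8.31 ± 0.23 and 8.18 ± 0.38. The growth factor gene Mdk, the chemokine receptor gene Ccr8, the retinoid receptor gene Rxrg and Tdrd9 changed by −6.05 ± 0.33, −5.91 ± 0.32, −5.34 ± 0.99 and −5.24 ± 0.42. Of dendritic genes 7 of 17 measured members rose and 2 fell (11 and 2 adjusted over the list alone; median log2 difference 1.94, camera adjusted p = 1.56e-05, adjusted p = 0.231 with an estimated correlation), and of MHC class II genes 9 of 10 measured members rose and 0 fell (9 and 0 adjusted over the list alone). Over this list, the median log2 difference was 5.12 (camera adjusted p = 4.52e-15, adjusted p = 0.0596 with an estimated correlation). T lineage genes fell: 0 of 10 measured members rose and 6 fell (0 and 6 adjusted over the list alone; median log2 difference −2.26, camera adjusted p = 1.98e-05, adjusted p = 0.122 with an estimated correlation), with Trbc1 at −4.57 ± 0.42, and on the ILC progenitor list 1 of 16 measured members rose and 6 fell (1 and 10 adjusted over the list alone). The median of these log2 differences was −0.99 (camera adjusted p = 2.28e-06, adjusted p = 0.314 with an estimated correlation). Erythroid genes had none of 11 called (median log2 difference 3.20, camera adjusted p = 0.0107, adjusted p = 0.733 with an estimated correlation). The count was 577 and 527 without CD127+ MHC class II− replicate 1 or 2, and the Rxrg call ended without any 1 library (adjusted p up to 0.109).

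**Figure D4:**
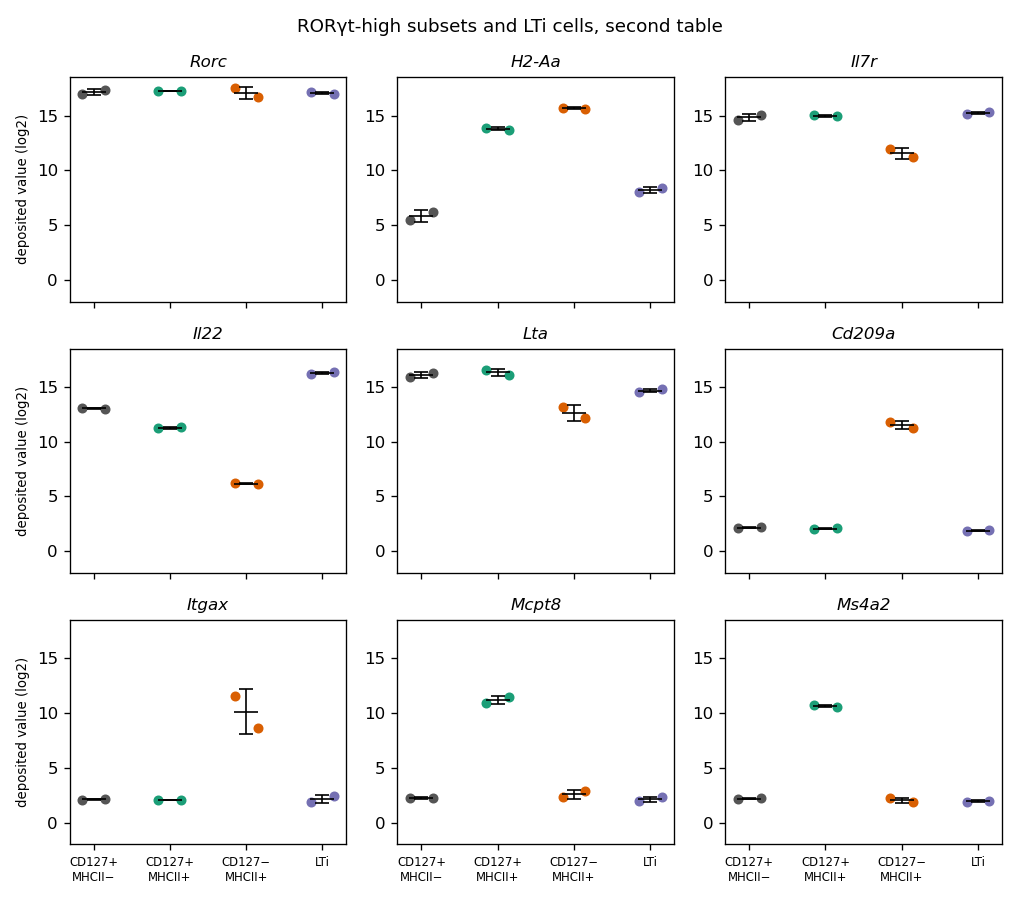
Deposited log2 value (y axis) of 9 genes in each library of the second table, by group (x axis; CD127+ MHC class II−, CD127+ MHC class II+, CD127− MHC class II+, LTi); points are libraries, and bars the mean ± SD of 2 libraries. Mcpt8 was at 11.19 in CD127+ MHC class II+ cells and below 3 in every library of the other groups.

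LTi cells of the second table had more Il22 and Nr4a3 than CD127+ MHC class II− liver cells. Few genes were called, which does not show that the groups are alike: simulation of this comparison recovered 11 of 100 genes changed by 1 on the log2 scale and 49 of 100 changed by 2. Nr4a3 rose from 2.51 ± 0.31 to 10.53 ± 0.49 (n = 2 each; 8.03 ± 0.31, adjusted p = 0.000518), and Il22 by 3.25 ± 0.14, adjusted p = 0.000518. The X-inactivation transcript Xist fell by 5.43 (SE 0.34, adjusted p = 0.00592). Of 15852 genes 8 were higher and 1 was lower, and 1349 had an unadjusted p under 0.05. The histone chaperone-like gene Nap1l5, which is imprinted, and the hypoxia-induced gene Hilpda rose by 4.70 ± 0.47 and 2.49 ± 0.24. H2-Aa differed by 2.35 ± 0.28, adjusted p = 0.0659. Col1a1 stood at 8.06 ± 3.48 in LTi libraries against 2.93 ± 0.11. Erythroid genes were lower (none of 11 called; median log2 difference −4.24, camera adjusted p = 1.95e-07, adjusted p = 0.504 with an estimated correlation), as were megakaryocyte genes (none of 5; median log2 difference −1.30, camera adjusted p = 0.000406, adjusted p = 0.295 with an estimated correlation) and myeloid and mast cell genes (none of 13; median log2 difference −1.75, camera adjusted p = 0.00247, adjusted p = 0.295 with an estimated correlation). Immediate-early genes had none of 14 called (median log2 difference −0.41, camera adjusted p = 0.0196, adjusted p = 0.664 with an estimated correlation), and proliferation genes none of 20 (median log2 difference 0.23, camera adjusted p = 0.203). Calls numbered 3 without CD127+ MHC class II− replicate 1, 32 without its replicate 2 (18.8% of them higher), and 3 and 14 without the first or second LTi library. The Nap1l5 and Hilpda calls ended without any 1 of the 4 libraries (adjusted p up to 0.308), and that of Xist without CD127+ MHC class II− replicate 1 (adjusted p = 0.120).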

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

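The alternative without the 2 libraries that held basophil transcripts was chosen after seeing the data; the others were planned. Of 318 called gene results named or listed, 197 held under every alternative, 121 were lost under at least 1, 82 of them on leaving out a library and 36 under another pseudocount, filter or scaling. Rescaling by TMM or median of ratios and other pseudocounts kept each count of called genes within 1.5 times. Comparisons are given in the order RORγt-mid against negative, high against mid, high against negative, LTi against high, knockout against wild type, CD127+ MHC class II+ against CD127+ MHC class II−, CD127− MHC class II+ against CD127+ MHC class II+ and against CD127+ MHC class II−, and LTi against CD127+ MHC class II−. With only both groups in the fit, which leaves fewer libraries for the spread, 522, 1051, 1710 and 332 genes were called in the first 4 and 4, 91, 290 and 1 in the last 4. An absolute log2 difference of at least 1 left 1127 (high against mid), 2042 (high against negative) and 83 (knockout). Array weights gave 4243 (high against mid), 1587 (LTi against high), 1152 (knockout), 368 and 582 (CD127− MHC class II+ comparisons) and 68 (LTi, second table); the cause was not tested. With them 41.9% of knockout calls were higher genes (26.2% of the 145), 88.6% of 35 for CD127+ MHC class II+ cells (76.9% of 26) and 77.9% for LTi in the second table (88.9% of 9). Without the filter on low values, where more genes were tested, 84 (knockout), 15, 447, 749 and 4 (second table) were called, and higher genes made up 39.3% of knockout calls and 76.7% of 874 for LTi against high (56.1% of 597; 77.1% with only both groups in the fit). With an estimated correlation, 10 of 43 and 0 of 27 list calls held by camera (23 and 12 at an unadjusted p under 0.05; fry called 40 and 18), and the genes higher in RORγt-high cells had the same median of −0.0858 in the knockout at p = 0.0700. Without the 2 libraries with basophil transcripts the counts were 1015, 2309, 3596, 430 and 168.

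Leaving out each library in turn gave 567 to 829, 1090 to 1856, 2171 to 3383, 320 to 504 and 32 to 84 calls in the first table and 10 to 19, 209 to 1547, 527 to 1704 and 3 to 32 in the second. List calls ranged from 38 to 46 and from 20 to 32. The median knockout difference ranged from −0.17 to −0.07 for the genes higher in RORγt-high cells and from 0.02 to 0.07 for those lower. The sign of 1 gene result turned: the Rorc difference between RORγt-high and RORγt-mid cells, not called, ranged from −0.13 to 0.0184.

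The sample numbers were not taken to pair the samples, since not every same-numbered pair correlated over 0.1; whether they share an origin stays open. Deviations of same-numbered libraries correlated at −0.083 to 0.223 in the first table, over 0.1 for 9 of 30 pairs (median 0.0268, against −0.0164 for other pairs), and at −0.0069 to 0.0406 in the second, over 0.1 for 0 of 6. Among the 15 libraries of the first table, 10 correlated best with one of their own number, a hint from the data and not the design. With the number as a replicate block, 882, 1686, 3175, 568 and 177 genes were called in the first table, and 6, 174 and 432 in the second, or 10, 11 and 371 with the number in the descriptions as a block; the cause was not tested. For LTi against CD127+ MHC class II− cells alone, no paired analysis was possible because the libraries of these groups share no number.

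Count tests on recovered whole reads, the comparison with only LTi replicates of the same label form and the comparison in the other table were planned and not run, because recovery of reads was not attempted with an unknown transform, each table holds 1 label form and no other table holds both groups. Depth is unknown, so how far it limits low genes is unknown too.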

Other observations

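The tests of bulk liver RNA, of handling, of a step back in the knockout, of the likeness between subsets and of LTi cells in both tables were chosen after the result they measure was seen. The basophil, Y-linked and plasmacytoid dendritic cell lists were written after the tables had been examined, the 15 held-out basophil genes and 4 Y-linked genes before their own values were looked at. The test of a step back followed 2 earlier tests of it, 1 for and 1 against, dropped because the choice of genes or libraries favoured their outcome.

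RORγt-mid cells differed from RORγt-high cells much as CD127− MHC class II+ cells differed from CD127+ MHC class II− cells in the other table, with no library in common. Across 12782 genes, which are not independent replicates, both log2 differences correlated at r = 0.528 (rho 0.358), and at 0.530 without the sort genes. Of 551 genes higher in CD127− MHC class II+ cells, 84.2% were higher in RORγt-mid than RORγt-high cells (median 0.83, camera p = 1.36e-32, p = 8.31e-06 with an estimated correlation). Of 453 genes lower there, 88.7% were lower in RORγt-mid cells (median −1.26, camera p = 1.22e-38, p = 8.06e-07 with an estimated correlation). One hypothesis is that a share of the RORγt-mid gate may hold cells like the CD127− MHC class II+ subset; libraries of pooled cells do not separate this from a profile that all RORγt-mid cells share.

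Genes that set LTi cells apart from RORγt-high cells in the first table moved as sets of called genes in the same direction against CD127+ MHC class II− cells in the second. The immediate-early list (median log2 difference 2.91 in the first table and −0.41 in the second) and the proliferation list (−0.41 and 0.23) did not. Of 334 genes higher in LTi cells, 284 (85.0%) were higher there too (median 0.68, camera p = 4.28e-36, p = 0.0132 with an estimated correlation). Of 260 lower genes, 73.8% were lower (median −0.29, p = 0.0282 with an estimated correlation). Few were called by limma in both: 4 of the 334 (Nr4a3, Il22, Hilpda and Nap1l5; 142 at an unadjusted p under 0.05) and 0 of the 260 (51 at an unadjusted p under 0.05). Both sets of LTi libraries held more Col1a1 than the liver cells (8.69 against 0.48, and 8.06 against 2.93). RNA of other fetal cells was therefore not separated from LTi cells here. H2-Aa stood at 11.75 to 11.91 in LTi libraries of the first table and at 7.99 and 8.41 in the second. The LTi sets may thus differ in their cells, although each table was normalized on its own. RORγt-negative libraries, besides B lineage genes, held genes of plasmacytoid dendritic cells, and 7 of 11 tested genes of that list were lower in RORγt-mid cells. Of the held-out basophil genes 7 of 12 tested were lower there, and 6 of 6 of those already seen, which were chosen because they showed it.

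Embryo sex genes differed between libraries. In the second table Xist stood at 9.27 to 10.51 in the 6 liver libraries, which also held the Y-linked gene Ddx3y at 11.18 to 12.46, and at 4.94 ± 0.54 in the 2 LTi libraries, which held Ddx3y at 13.03 ± 0.19. In the first table Ddx3y ranged from 0.93 to 9.22 among RORγt-high libraries and from 1.01 to 1.27 among RORγt-mid libraries. Of 4 Y-linked genes, 2 were higher in both LTi libraries than in every liver library, so the sex of the embryos and a change of Xist in LTi cells cannot be told apart. The labels give no sex.

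CD127+ MHC class II+ libraries held Mcpt8, Prss34, Cpa3, Hdc and Ms4a2 at 11.19 ± 0.35, 11.03 ± 1.5, 11.44 ± 0.69, 12.43 ± 0.31 and 10.65 ± 0.11. Carry-over of bulk liver RNA would keep basophil and erythroid genes in 1 ratio. For the 7 basophil genes already seen, their difference from erythroid genes was 6.19 higher on the log2 scale than in the other liver subsets (lowest −0.26 against highest −1.47). These 7 genes were chosen after their values were seen, which favours such a difference, so this test does not decide on carry-over. RNA of basophil-lineage cells inside the gate may account for the pattern: 8 of 15 held-out basophil genes (53.3%) were higher by 1 or more (median 1.43), between the bounds set in advance, so these cells and RORγt-high cells with basophil genes cannot be told apart. What keeps it open is that 5 of the 15 genes already had a mean of at least 50 on the linear scale in CD127+ MHC class II− cells, where a rise is harder to see, and 1 stands in another list. In RORγt-negative libraries, 13 of 15 (86.7%, median 2.13) were higher than in RORγt-mid libraries, as basophil-lineage cells in that gate would give; the lineage gate should remove such cells, but its antibodies are not given, and no biological explanation was tested.

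Immediate-early genes, taken as the mean of 11 genes over that of 9995 reference genes in the same library, stood at 3.04 ± 0.23 in LTi libraries of the first table and between −0.81 and 0.50 in the liver groups there. The highest of these liver groups was the knockout (0.50 ± 0.05, against −0.52 ± 0.32 in wild-type RORγt-mid cells). Handling and loss of RORγt were not told apart for that rise. In the second table the liver groups stood at 3.09 ± 0.41, 3.14 ± 0.24 and 3.41 ± 0.38, and LTi cells at 2.79 ± 0.12. Levels of 1 table against the other are approximate, because each table was normalized on its own. The list differed between LTi and CD127+ MHC class II− cells by a mean of −0.31 in the second table, against 3.47 between LTi and RORγt-high cells in the first. A candidate explanation is handling of the cells that differed between sets of libraries. A difference of tissue or cell type alone would raise these 11 genes in LTi cells of the second table too. The mean of −0.31 there argues against such a difference as the only cause in both sets of libraries. It does not decide on the first table. The liver groups of the second stood at the LTi level already, which could hide such a difference, and the liver cells compared were not the same gate. How large a part tissue or cell type had in the first table stays open, and both change together in these groups.

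The 107 genes lower in the knockout could come from knockout RORγt-mid cells standing earlier in the RORγt series, which would move every gene of the step from RORγt-negative to RORγt-mid cells back by about the same fraction. Over all 895 genes called at that step the median fraction was 0.167 (quartiles −0.0682 and 0.468), although the shared RORγt-mid libraries raise it, against a lower quartile of 0.676 among the 41 genes that rose at the step and were lower in the knockout, whose choice raises theirs. With a step back of 0.167 taken off every gene, 95 of the 107 stayed called over all genes, and 79 with 0.468. However, 65 of the 107 were not called between RORγt-mid and RORγt-negative cells. Taking off a fraction of a small difference can hardly end a call, so these counts do not decide on a step back. A step back, as the whole cause or a part of it, and a dependence of these genes on RORγt stay open: 84.1% of the 107, against 51.4% of all tested genes, were higher in RORγt-high than in RORγt-negative cells. A different makeup of the gate stays open too and was not tested: no member of the hepatocyte or erythroid list was called, and both lists were higher in the knockout only at the preset correlation (adjusted p = 0.263 and 0.342 with an estimated correlation).

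Each comparison of 3 against 3 libraries allows 10 splits, too few for a share under 0.05. The real counts of called genes and the highest of the other splits were 895 and 3 (RORγt-mid against negative), 1745 and 388 (high against mid), 3113 and 2 (high against negative), 597 and 1 (LTi against high) and 145 and 0 (knockout), so 1 split of 10, the real one, reached the real count.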
